A study of Bacillus subtilis with 12 samples.

How the data were processed

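RNA was measured by sequencing in 12 libraries of Bacillus subtilis, 3 in each of 4 groups: wild type, the yacP deletion, and the deletion strain with a plasmid copy of yacP grown without or with IPTG. Per the labels' protocols, cultures grew at 37 °C in 2xYT with shaking, with mls or kan as antibiotic and with or without 1 mM IPTG, and were harvested at an OD600 of 0.6. The labels do not say which antibiotic each strain received. Per the labels' protocols, RNA came from 20 mL of culture, ribosomal RNA was removed with a RiboZero kit, stranded libraries were made with a Smarter kit, and the 12 samples were pooled for sequencing on a HiSeq2000. Per the submitters' processing notes, CASAVA 1.8, FastQC, Bowtie and DESeq2 were used. The genome build, the counting tool and its strand setting are not given in the sources used here.

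The deposited tables hold raw counts, one column per library, as whole numbers per annotated feature. The authors' log2 fold changes and their adjusted p-values stand in the same deposited tables, per the file headers. The authors' signs run the other way from those used here, wild type over deletion and without IPTG over with IPTG. Their base mean was identical for all 5875 features in both tables. Their adjusted p-value was NA for 2979 features in the deletion comparison and for 2400 in the IPTG comparison. The tables list 5875 features: 4230 genes with a BSU number, 1583 S features, 52 other RNAs and 10 tRNAs. S features are transcribed segments that the deposited annotation lists beside the genes, with a class such as between genes ("inter") or independent ("indep"). No feature is a ribosomal RNA gene, and 87 features have 0 counts in every library. Coordinates are those of the deposited annotation, 1-based, in the version its header calls V3. Names missing from the tables were taken by locus tag from RefSeq assembly ASM904v1, which matched 4287 features and gave the only name of 400. Of all features, 1262 overlap a feature on the opposite strand, so their counts depend on the unstated strand setting. Another feature on the same strand is overlapped by 966, whose counts depend on how the unstated counting tool treats shared reads.

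Library totals ranged from 7468757 to 16944517 counts. A limit of 3 counts corresponds to 0.177 to 0.402 counts-per-million (CPM) per library. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries within a group had Spearman correlations across features of 0.964 or more.

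Counts of all 12 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter by group and the quasi-likelihood test. The filter kept 4720 features, the common dispersion was 0.0362 (a biological coefficient of variation of 19%) and 8 residual degrees of freedom remained. TMM factors ranged from 0.931 to 1.102. P-values were adjusted by Benjamini-Hochberg over the tested features, with a threshold of 0.05. Values are log2 fold changes ± standard error (SE, from the quasi-likelihood F), or CPM ± SD, with n = 3 libraries per group unless stated. A called feature is one past the threshold, and the tests are two-sided unless stated. The contrasts were deletion minus wild type, with minus without IPTG, without IPTG minus deletion, and with IPTG minus wild type. A further contrast tested the deletion effect minus the effect of lacking IPTG, and without IPTG minus wild type was fitted for the levels of yacP, the features around yrzI and yheI, and the genes weighed in the closing part. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

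Of 35 gene lists written down with the design, 31 had 3 or more measured members and were tested with camera (limma 3.58.1) on log2-CPM with a prior count of 2 and a preset correlation of 0.01. The adjustment ran over the lists, in the deletion and IPTG comparisons. The other 4 lists are given gene by gene or had no tested member: the rae1 locus, the reported Rae1 targets, the ICEBs1 element and the ribosomal RNA genes. The tested lists were ribosomal proteins, translation and ribosome assembly factors, aminoacyl-tRNA synthetases, RNA decay, motility and chemotaxis, biofilm matrix, competence, early sporulation, heat shock, SigB general stress, SOS response, cell envelope stress and iron starvation (Fur). Metabolic lists were purine, pyrimidine, arginine, branched-chain amino acid, tryptophan and histidine synthesis, methionine and cysteine metabolism, TCA cycle, glycolysis, aerobic respiration, anaerobic and nitrate metabolism, carbon source utilisation and phosphate starvation. The rest were multidrug transport and antibiotic resistance, the PBSX and SPbeta prophages, the skin element, cannibalism and bacteriocins, and extracellular enzymes. The reported Rae1 targets (yrzI, S1025, S1027, yheJ, yheI and yheH) come from knowledge of work on Rae1 that may rest on these libraries, so their count is not independent evidence.

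In the deletion and IPTG comparisons, the genes to be named were yacP, the 12 called features with the largest change each way whose groups did not overlap, all members of the rae1 locus and reported targets, and the 10 features changed in opposite ways with the largest smaller change. From a list past its test, or with 3 or more called members, up to 4 members with the smallest p were added. In the other comparisons 5 features each way were named. After the data were seen, 2 example members with the smallest p were added there for each list with 10 or more called members. Any other gene named in the text was chosen after its values were seen: the neighbours of the named genes drawn in the map, fruA in the deletion comparison, and the genes named in the last part.

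The design, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives chosen then were relative log expression scaling (RLE) in edgeR, DESeq2 1.42.0, no filter, a filter of 10 CPM in 3 libraries, the tRNA features left out, the top 10 features left out of the scaling, only the libraries of the groups compared, the replicate letter as a block, and each library left out in turn. For the lists they were an estimated correlation and fry. Added after seeing the data were fits without both plasmid-strain libraries of letter D and fits of the 6 libraries compared with the letter as a block.

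The letters A, B and D recur in every group. Between the plasmid strain's libraries with and without IPTG, the deviations from the group means correlated across features at 0.42 for A, 0.65 for B and 0.80 for D. Each is over 0.1, the limit used, so these letters were taken to pair those samples, from the data and not from a label. The pairing is weakest for A, whose highest correlation with another letter was 0.43. For B it was 0.42 and for D -0.55. Deviations of the 3 libraries of a group sum to 0, so a shift of D in both groups also correlates A and B. These values thus bear mainly on D, and the pairing of A and of B is less sure. Where the paired fit of these 6 libraries moved the count of called members of a list by over 1.5 times, its count is given beside it.

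The code was tested on simulated data made from each feature's mean over all libraries and the real library sizes, with 4665 features tested. In the deletion comparison it recovered 32.8% of 67 features changed 1.5-fold, 89.6% of 67 changed 2-fold and 92.4% of 66 changed 4-fold, and it called 0.11% of the unchanged ones. In the IPTG comparison the shares were 34.3%, 68.7% and 97%, with 0.04% of the unchanged ones called. The simulated libraries varied independently and held no strain difference, outlying library or structure by letter. These shares check the code and need not hold for the real libraries. The tables that hold a single group's columns repeat these counts and were left out.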

Results

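RNA levels were measured in 12 libraries of Bacillus subtilis, in 4 groups of 3 libraries lettered A, B and D. The groups were the wild-type strain W168, its yacP deletion, and the deletion strain carrying yacP on the plasmid pDG-yacP, grown without or with 1 mM IPTG, an inducer of promoters under lac control. The gene yacP, also called rae1, encodes the ribosome-associated endoribonuclease Rae1. Wild-type libraries A, B and D held 9261931, 15762748 and 16944517 counts. Those of the deletion held 13094296, 12793942 and 12103235. The plasmid strain's libraries held 11582572, 9788780 and 8695169 counts without IPTG and 7468757, 10095485 and 10720644 with it. Library D of the plasmid strain stood apart from A and B in both of its groups. Its features differed from those of the other libraries of the group by a median of 0.24 without IPTG (absolute log2), against 0.14 for A and 0.18 for B. With IPTG the median was 0.17, against 0.12 for A and 0.14 for B. Over the other libraries of all groups it was 0.09 to 0.18, so by this measure D exceeded them only without IPTG. The chi-square per degree of freedom of its pairs ran from 50.99 to 143.93, against 4.33 to 35.64 for all other pairs within a group.

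The transcript of yacP (BSU00970, 116025 to 116537, plus strand) followed the labels in all 12 libraries. It lay at 106 ± 8.9 CPM in wild type, 6.21 ± 1.65 CPM in the deletion, 260 ± 56.3 CPM in the plasmid strain without IPTG and 67600 ± 1520 CPM with IPTG (mean ± SD, n = 3 each). Without IPTG, yacP RNA in the plasmid strain was above the wild-type level by a log2 fold change of 1.30 (edgeR adjusted p = 0.000328). With IPTG, yacP took 6.8848% to 6.9163% of all counts in a library, and the 10 most abundant features together took 20.0% to 20.5%, against 14.2% to 15.6% in the other groups.

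**Figure D1:**
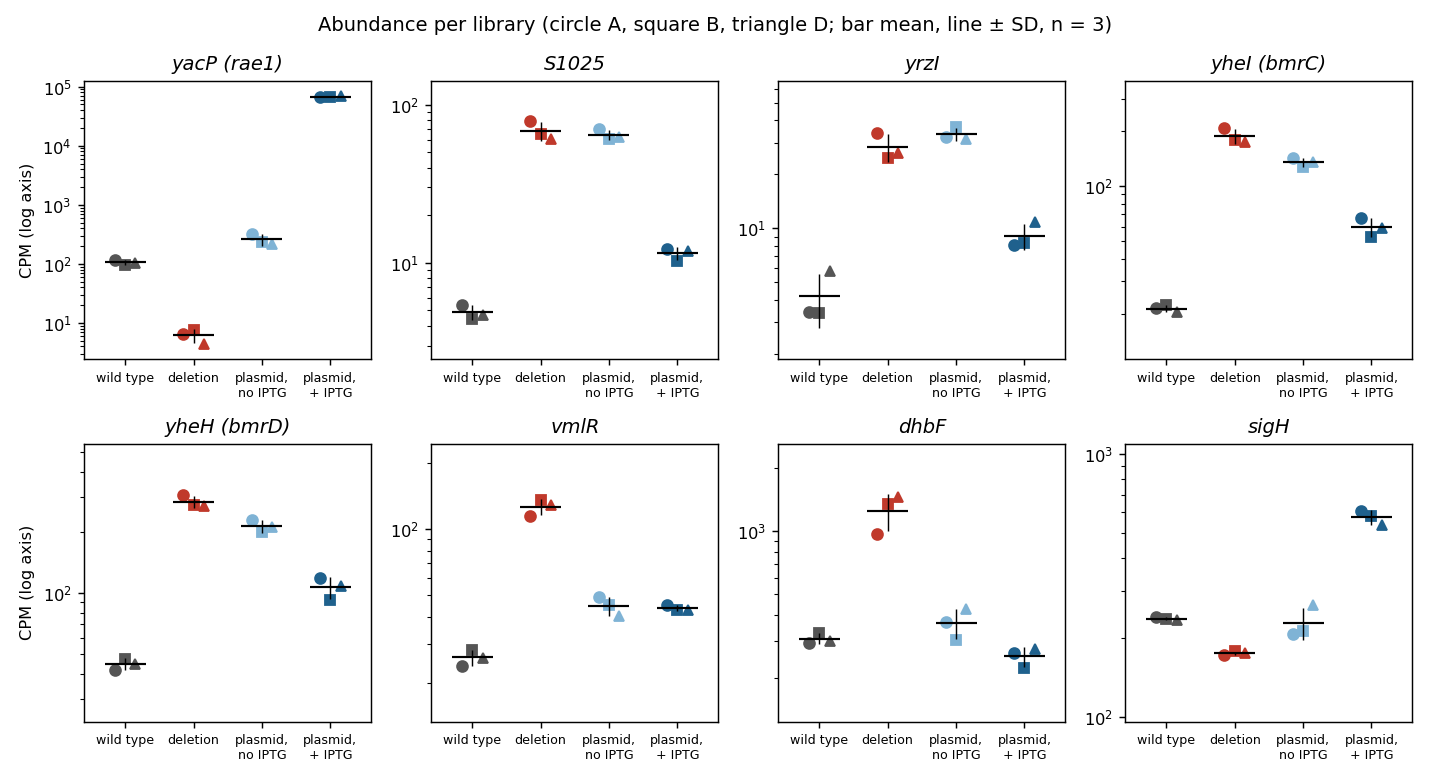
CPM per library on a log axis for yacP, S1025, yrzI, yheI, yheH, vmlR, dhbF and sigH in the 4 groups (circle A, square B, triangle D; bar, mean; line, ± SD; n = 3). S1025 goes from 4.86 CPM in wild type to 67.8 CPM in the deletion, lies at 64.3 CPM in the plasmid strain without IPTG and at 11.5 CPM with IPTG.

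The deletion was compared with wild type to find the transcripts that change when Rae1 is missing. Since the labels do not assign the antibiotics to strains, the antibiotic may differ between these groups too. If it does, its effect cannot be told apart from that of the deletion. Features that rose most lay side by side at a pair of loci. Around yrzI (BSU27190, 2778923 to 2779072, minus strand), S1025 (2778792 to 2778922) rose by 3.81 ± 0.13 (log2 fold change ± SE, n = 3 per group; edgeR adjusted p = 4.23e-08), S1024 (2778574 to 2778790) by 3.36 ± 0.12, yrzI itself by 2.73 ± 0.22 and S1026 (2779073 to 2779163) by 1.85 ± 0.16. The annotation places S1025 and S1026 between genes and calls S1024 independent. At the other locus, yheI (BSU09710, 1045318 to 1047075, plus strand) rose by 3.14 ± 0.10 (adjusted p = 4.23e-08) and yheH (BSU09720, 1047072 to 1049093) by 2.66 ± 0.10. These genes encode a multidrug ABC transporter and overlap by a few bases. Just upstream of yheI, S341 (1045199 to 1045317) went from 0.202 ± 0.14 CPM, or 1 to 3 counts per library, to 2.75 ± 0.772 CPM (adjusted p = 0.00023). The outer neighbours S1027 (-0.08 ± 0.14, adjusted p = 0.877) and yheJ (0.16 ± 0.17, adjusted p = 0.733), both on the list of reported Rae1 targets, were not called. Transcripts of vmlR (BSU05610, 604736 to 606379, minus strand), an ABC-F protein that protects ribosomes from antibiotics, rose by 2.27 ± 0.10 (adjusted p = 1.47e-07), and the annotation lists the antisense feature S197 over this gene. The deletion itself read as a fall of yacP by 4.08 ± 0.21 (adjusted p = 8.03e-07).

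**Figure D2:**
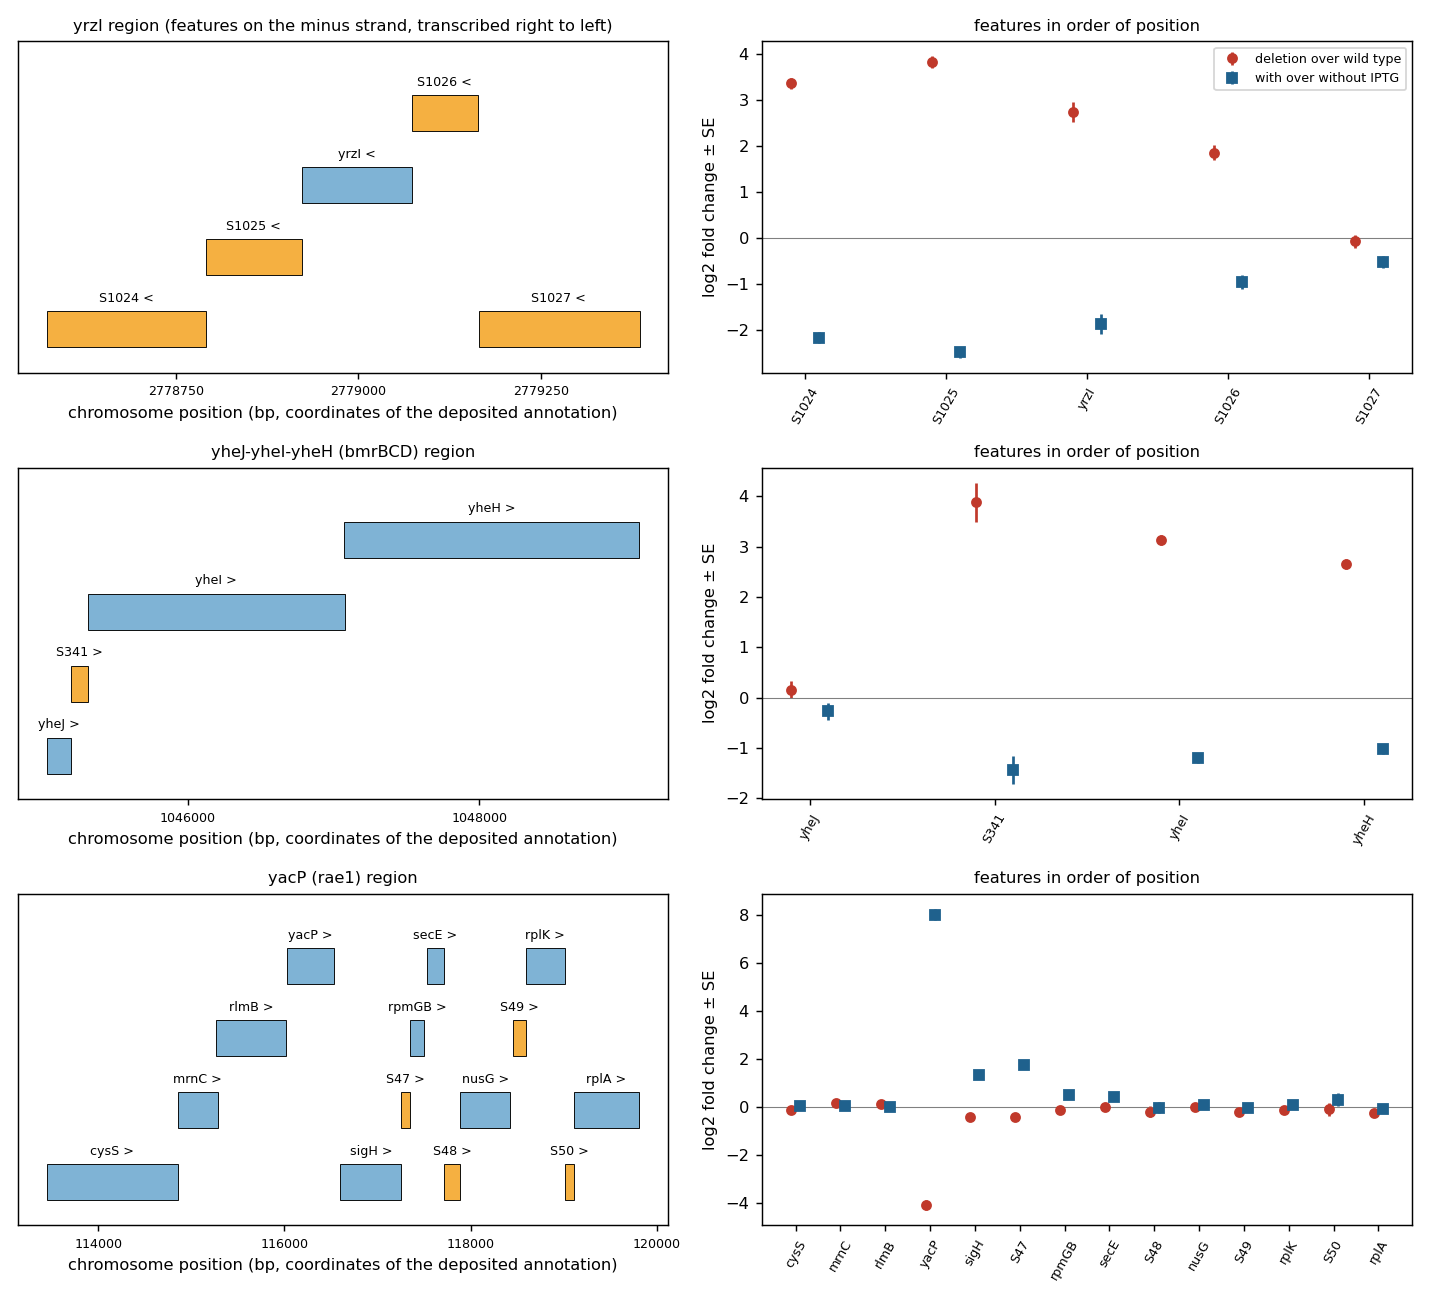
Maps of the yrzI, yheI and yacP loci to scale (position in bases, arrows by strand) with the log2 fold change ± SE of each feature in the deletion and IPTG comparisons. S1024, S1025, yrzI and S1026 lie above 0 in the deletion and below 0 with IPTG, while S1027 and yheJ lie at -0.08 and 0.16 in the deletion.

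Iron starvation genes, under the repressor Fur, rose together in the deletion: 17 of 28 measured members rose and 0 fell, and 21 rose when adjusted over the list alone. Among them, dhbF rose by 2.02 ± 0.16 (adjusted p = 6.43e-05), dhbB by 1.88 ± 0.16 and dhbA by 1.84 ± 0.16, all in the synthesis of the siderophore bacillibactin. The flavodoxin gene ykuP rose by 1.40 ± 0.12. The list's median was 0.50 and camera's adjusted p = 4.38e-21 with the preset correlation, against an adjusted p = 0.155 with an estimated correlation. In the motility and chemotaxis list, 18 of 48 members rose and 0 fell, and 29 rose when adjusted over the list alone. The flagellar switch genes fliM and fliY rose by 0.48 ± 0.06 and 0.42 ± 0.05, and the export gene flhA by 0.44 ± 0.06. Flagellin, hag, rose by 0.49 ± 0.08 (adjusted p = 0.00757). The motility median was 0.33 (camera adjusted p = 6.37e-15; adjusted p = 0.069 with an estimated correlation).

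Lists with smaller medians also passed camera's test in the direction up. Other splits of the same 6 libraries, which called 0 features, passed 3 to 13 lists, against 14 in the real split. A pass with the preset correlation alone thus does not show that a list moved with the deletion. Of 21 biofilm genes, 1 rose (1 when adjusted over the list alone), yuaB for a surface protein, by 0.51 ± 0.10, with a list median of 0.26 (adjusted p = 0.0059; adjusted p = 0.155 with an estimated correlation). Among 24 cannibalism and bacteriocin genes, 2 rose (4 when adjusted over the list alone), sunA for sublancin by 1.21 ± 0.21 and albA by 0.33 ± 0.07, with a median of 0.13 (adjusted p = 0.00606; adjusted p = 0.131 with an estimated correlation). The heat shock list had 1 of 19 members higher (1 when adjusted over the list alone), ctsR, by 0.30 ± 0.07, and a median of 0.10 (adjusted p = 0.00507; adjusted p = 0.401 with an estimated correlation). Of 42 cell envelope stress genes, 4 rose (5 when adjusted over the list alone), the exporter genes yknW, yknX, yknY and yknZ, by 0.77 ± 0.15, 0.72 ± 0.16, 0.76 ± 0.17 and 0.75 ± 0.15. That list's median was 0.13 (adjusted p = 0.028; adjusted p = 0.571 with an estimated correlation), and its call ended without wild-type library A (adjusted p = 0.0865) or deletion library D (adjusted p = 0.123).

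Apart from yacP, the called transcripts that were lower in the deletion changed less. Among these called features, those that fell most were S1290 (log2 fold change -1.71 ± 0.36, adjusted p = 0.0258), a feature antisense to the opuB genes at 0.905 CPM in wild type, levB for a levanase (-0.90 ± 0.13, adjusted p = 0.00319) and yqjL (-0.89 ± 0.10, adjusted p = 0.000639). Some features that were not called had larger falls than levB. The carbon source gene fruA went from 1850, 1150 and 2000 CPM in wild type (A, B, D) to 241, 467 and 591 CPM. The cell wall hydrolase gene lytE fell with -0.60 ± 0.13 and bcrC, for a pyrophosphate phosphatase of cell wall synthesis, with -0.65 ± 0.13. Of 26 aminoacyl-tRNA synthetase genes, 2 fell (6 when adjusted over the list alone), aspS with -0.27 ± 0.06 and lysS with -0.25 ± 0.05, with a median of -0.10 (camera adjusted p = 1.76e-05; adjusted p = 0.155 with an estimated correlation). Pyrimidine synthesis had 0 of 12 called and 2 lower when adjusted over the list alone (5 lower at an unadjusted p under 0.05 in edgeR, 3 called by DESeq2). Its median was -0.56 (adjusted p = 0.000125; adjusted p = 0.184 with an estimated correlation). A gene of that pathway for carbamoyl phosphate synthase, pyrAA, had a value of -1.33 ± 0.37 (adjusted p = 0.0796). Phosphate starvation had a median of -0.24 over 19 genes (adjusted p = 0.00507; adjusted p = 0.184 with an estimated correlation), with 0 called (0 when adjusted over the list alone, 3 lower unadjusted, 0 in DESeq2).

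Camera's call for 5 further lists rested on single libraries. Over 32 PBSX prophage genes the median was -0.23 (adjusted p = 0.000619; adjusted p = 0.571 with an estimated correlation), and the adjusted p was 0.707 without wild-type library A. Purine synthesis, 24 genes, had a median of -0.25 (adjusted p = 0.00697; adjusted p = 0.571 with an estimated correlation), and an adjusted p of 0.0557 without deletion library D. Of 27 SigB general stress genes, 1 fell (3 when adjusted over the list alone), ctc, with -0.24 ± 0.06, with a median of -0.04 (adjusted p = 0.0149; adjusted p = 0.259 with an estimated correlation). Its adjusted p was 0.0812 without wild-type D and 0.078 without deletion B. For the SOS response, 22 genes, the median was -0.06 (adjusted p = 0.028; adjusted p = 0.208 with an estimated correlation), and the adjusted p was 0.0812 without wild-type D and 0.0894 without deletion A. Anaerobic and nitrate metabolism, 16 genes, had a median of -0.10 (adjusted p = 0.028; adjusted p = 0.317 with an estimated correlation). Its adjusted p was 0.0654 without wild-type B and 0.127 without deletion D. In edgeR, PBSX, purine, SOS and anaerobic genes had 0 called (0 when adjusted over each list alone). Unadjusted, 5 PBSX, 2 purine, 3 SOS and 4 anaerobic genes were lower and 1 SOS gene was higher, and DESeq2 called 0, 0, 1 and 1 lower and 1 SOS gene higher.

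The other lists did not pass camera's test in the deletion. Multidrug transport and antibiotic resistance had 3 of 23 members higher, vmlR, yheI and yheH, and 1 lower when adjusted over the list alone; its median was -0.02, its mean 0.30 and its direction up (adjusted p = 0.184). SPbeta prophage had 3 of 49 higher (4 when adjusted over the list alone), sunA, yolJ (0.75 ± 0.14) and yomJ (0.43 ± 0.09), and a median of 0.14 (adjusted p = 0.0866). The skin element had 1 of 20 higher (3 when adjusted over the list alone), yqcG by 0.27 ± 0.06, with a median of 0.14 (adjusted p = 0.153), and competence 0 of 22 in edgeR (3 higher when adjusted over the list alone, 8 higher and 1 lower unadjusted, 2 higher by DESeq2), with a median of 0.06 (adjusted p = 0.1). Ribosomal proteins had 1 of 50 lower (1 when adjusted over the list alone), rplA, by a log2 fold change of -0.26 ± 0.06, and early sporulation 1 of 26 (1 when adjusted over the list alone), sigH, the sigma factor gene of early sporulation, by -0.43 ± 0.09. Their medians were -0.01 (adjusted p = 0.107) and 0.03 (adjusted p = 0.634). Carbon source utilisation had a median of -0.14 over 81 genes (adjusted p = 0.184), the TCA cycle 0.19 over 15 (adjusted p = 0.579) and extracellular enzymes 0.11 over 19 (adjusted p = 0.339). Medians were -0.05 for translation factors (adjusted p = 0.135), -0.07 for branched-chain amino acids (adjusted p = 0.359), -0.07 for tryptophan and histidine (adjusted p = 0.184) and 0.12 for methionine and cysteine (adjusted p = 0.843). RNA decay (adjusted p = 0.805), arginine (adjusted p = 0.925), glycolysis (adjusted p = 0.819) and respiration (adjusted p = 0.359) had medians and means from -0.01 to 0.03 with the test's direction down. In these last 11 lists edgeR called 0 members, also when adjusted over each list alone, while 0 to 4 members per list passed an unadjusted p under 0.05 and DESeq2 called 0 to 2. ICEBs1 genes, 23 found, were too low to test, and the tables hold 0 ribosomal RNA genes. Of the 17 genes at the rae1 locus, 4 fell (5 when adjusted over the list alone): yacP, sigH, radA for DNA repair (-0.33 ± 0.06) and rplA. Of the 6 reported Rae1 targets, 4 rose (4 when adjusted over the list alone), S1025, yrzI, yheI and yheH, and S1027 and yheJ were not called, which is not independent evidence.

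In all, edgeR called 195 features in the deletion, 156 higher and 39 lower, 178 of them genes and 17 S features. By size, 24 were higher and 2 lower by 2-fold or more. At an unadjusted p under 0.05 there were 826, and 29.5% of features had groups that did not overlap, where chance gives 10%. The authors' table lists 290 at an adjusted p-value under 0.05, of which 160 are among the 195. Without 1 library the count was 128, 72 and 72 (wild type A, B, D) or 103, 82 and 80 (deletion A, B, D). Without both plasmid-strain libraries D it was 514, and 201 of 329 were higher with DESeq2. The calls of sigH, yknX, yknY, yknZ, albA and ctc ended without any 1 of the 6 libraries (highest adjusted p = 0.0822, 0.113, 0.148, 0.0929, 0.134 and 0.143). Those of yknW, ctsR, lytE, bcrC, aspS, lysS, rplA, radA, yuaB, yolJ and S1290 ended when any of 2 to 5 of these libraries was left out singly (highest from 0.0554 for radA to 0.154 for aspS), and that of sunA without wild-type D (0.0505).

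The plasmid strain with IPTG was compared with the same strain without it to see which transcripts change when yacP is supplied. No culture labelled as grown with IPTG lacked the plasmid, so effects of IPTG itself cannot be told apart from those of supplied yacP. Transcripts around yrzI and at yheI fell, S1025 with a log2 fold change of -2.49 ± 0.12 (± SE, n = 3 per group; edgeR adjusted p = 1.21e-06), S1024 with -2.18 ± 0.12, yrzI with -1.88 ± 0.21 and S1026 with -0.96 ± 0.15. The transporter genes yheI and yheH fell with -1.19 ± 0.10 (adjusted p = 7.46e-05) and -1.01 ± 0.10. S341 went from 3.61 ± 0.343 to 1.35 ± 0.298 CPM (-1.43 ± 0.28, adjusted p = 0.0487). The endoglucanase gene bglC fell with -1.17 ± 0.15 and hag with -0.56 ± 0.09, and the annotation lists S122 antisense to bglC. Higher with IPTG were yacP, by 8.02 ± 0.24 (adjusted p = 2.11e-08), and its downstream neighbours sigH (BSU00980, 116600 to 117256), by 1.34 ± 0.09, S47 (117257 to 117348), by 1.75 ± 0.13, rpmGB for a ribosomal protein, by 0.52 ± 0.08, and secE for the protein translocase, by 0.42 ± 0.06. Farther downstream, nusG (0.08 ± 0.12, adjusted p = 0.93) and rplK (0.08 ± 0.05, adjusted p = 0.749) were not called. Away from that locus, yqjD and yqjE rose by 1.59 ± 0.05 and 1.58 ± 0.09, S906, antisense to yqjF, by 1.30 ± 0.13, lytH for a cell wall endopeptidase by 1.29 ± 0.17, and spo0B of the sporulation phosphorelay by 0.51 ± 0.08.

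Lists fixed in advance had few called members with IPTG in the fit of 12 libraries; paired counts are from the fit of the 6 plasmid-strain libraries with the letter as a block. Iron starvation genes had 0 of 28 called (0 when adjusted over the list alone; 7 lower unadjusted in edgeR, 1 called by DESeq2; 6 lower paired) and a median of -0.16 (camera adjusted p = 5.43e-06; adjusted p = 0.575 with an estimated correlation), with dhbF at -0.53 ± 0.16 (adjusted p = 0.282; paired adjusted p = 0.00025). Of 48 motility genes 1 fell, hag, 5 fell when adjusted over the list alone and 3 fell paired; the median was -0.14 (adjusted p = 2.84e-05; adjusted p = 0.268 with an estimated correlation). Glycolysis had 0 of 17 called and 3 lower when adjusted over the list alone (5 unadjusted, 3 by DESeq2; 4 lower paired), with a median of -0.12 (adjusted p = 5.44e-05; adjusted p = 0.268 with an estimated correlation). The PBSX median was -0.18 over 32 genes (adjusted p = 0.000191; adjusted p = 0.857 with an estimated correlation) and the SOS median 0.08 over 22 (adjusted p = 0.0034; adjusted p = 0.268 with an estimated correlation). Both had 0 called (0 when adjusted over each list alone, 3 unadjusted each, 0 by DESeq2), while the paired fit called 6 PBSX genes lower and 0 SOS genes. Early sporulation had 2 of 26 higher (2 when adjusted over the list alone), sigH and spo0B, and a median of 0.06 (adjusted p = 0.0132; adjusted p = 0.268 with an estimated correlation; adjusted p = 0.132 without library D with IPTG).

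Some list calls with IPTG rested on single libraries of the plasmid strain. TCA cycle genes in library D lay 0.86 above the other 2 libraries of its group without IPTG and 0.64 above them with IPTG (median log2), and their median change was -0.29 over 15 genes (camera adjusted p = 0.0287; adjusted p = 0.912 with an estimated correlation). The adjusted p was 0.823 without library D lacking IPTG, and 0.161 and 0.489 without libraries A and B with IPTG. Aerobic respiration had a median of -0.08 over 32 genes (adjusted p = 0.0287; adjusted p = 0.794 with an estimated correlation). Its adjusted p was 0.058 and 0.496 without libraries A and D lacking IPTG, and 0.161 and 0.121 without A and B with IPTG. For phosphate starvation the median was 0.24 over 19 genes (adjusted p = 0.0228; adjusted p = 0.318 with an estimated correlation), with adjusted p of 0.0742 without library D lacking IPTG and 0.434 without B with IPTG. Anaerobic metabolism had a median of 0.11 over 16 genes (adjusted p = 0.0197; adjusted p = 0.318 with an estimated correlation), with 1 gene higher when adjusted over the list alone and adjusted p of 0.109 and 0.0839 without library B lacking or with IPTG. Its nitrite reductase gene nasD had a value of 1.00 ± 0.21 (adjusted p = 0.0788; paired adjusted p = 0.00744). In edgeR the TCA, respiration, phosphate and anaerobic lists had 0 called over all genes and, but for that 1 anaerobic gene, 0 when adjusted over each list alone, with 0, 2, 1 and 4 past an unadjusted p under 0.05 and 0, 0, 1 and 0 called by DESeq2. In the paired fit, 8 TCA genes and 1 respiration gene were lower, and 5 phosphate and 4 anaerobic genes were higher. Without both libraries D, the median of the anaerobic list was 0.18 and that of early sporulation 0.01.

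The remaining lists did not pass with IPTG. Carbon source genes in library D lay 1.97 and 1.53 above the other 2 libraries of its group without and with IPTG. Their median change was -0.36 over 81 genes (camera adjusted p = 0.12), with 21 of 74 lower in the paired fit; the fit of 12 libraries called 0 and, without both libraries D and unpaired, 1 was lower, with a median of -0.17. Purine genes lay at -0.50 and -0.29 in library D against the other 2, with a median change of -0.12 (adjusted p = 0.12; median -0.21 without both libraries D). Pyrimidine genes lay farthest out in library A, at 0.67 and 0.35 without and with IPTG, against -0.41 and 0 in library D, with a median change of 0.20 (adjusted p = 0.0934; median 0.04 without both libraries D). Ribosomal proteins had 1 of 50 higher, rpmGB, and 2 higher and 1 lower when adjusted over the list alone (median -0.01, adjusted p = 0.84). Translation factors had 1 of 24 higher (2 when adjusted over the list alone), the ribosome assembly GTPase gene obg by 0.41 ± 0.07, with a median of 0.01 (adjusted p = 0.346). Cannibalism and bacteriocins had 1 of 24 higher (1 when adjusted over the list alone), bacE by 0.56 ± 0.10, with a median of 0.07 (adjusted p = 0.136). Multidrug transport had 2 of 23 lower (2 when adjusted over the list alone), yheI and yheH, with a median of 0.01, a mean of -0.12 and the direction down (adjusted p = 0.183). Extracellular enzymes had 1 higher when adjusted over the list alone (median -0.04, mean -0.06, direction up, adjusted p = 0.989), and SPbeta 1 lower (median 0.02, adjusted p = 0.84). Medians were 0.02 for aminoacyl-tRNA synthetases (adjusted p = 0.84), 0.01 for competence (adjusted p = 0.975), 0.06 for SigB (adjusted p = 0.223), -0.02 for arginine (adjusted p = 0.94) and -0.03 for tryptophan and histidine (adjusted p = 0.84). The median and the test differed in sign for branched-chain amino acids (0.05, direction down, adjusted p = 0.975), methionine and cysteine (0.04, down, adjusted p = 0.918) and heat shock (0.01, down, adjusted p = 0.84). Medians were 0 for RNA decay (adjusted p = 0.975), biofilm (adjusted p = 0.84), cell envelope stress (adjusted p = 0.84) and the skin element (adjusted p = 0.84), with directions up, up, down and up. Carbon, purine, pyrimidine, extracellular, SPbeta and the 12 lists of the last 3 sentences had 0 members called in edgeR, also when adjusted over each list alone except 1 gene each of SPbeta and extracellular enzymes, with 0 to 4 past an unadjusted p under 0.05 and 0 to 2 called by DESeq2. The paired fit called 1 purine and 1 SigB gene higher, and 2 purine, 2 RNA decay, 1 heat shock and 1 SPbeta gene lower. It also called 2 ribosomal protein genes higher and 4 lower, and 2 translation factor genes higher and 1 lower. At the rae1 locus, 4 of 17 genes rose (4 when adjusted over the list alone), yacP, sigH, rpmGB and secE. Of the 6 reported Rae1 targets, 4 fell (5 when adjusted over the list alone, 5 by DESeq2), which is not independent evidence. In the fit of 12 libraries, S1027 (-0.53, adjusted p = 0.192) and yheJ (-0.27, adjusted p = 0.745) were not called. The paired fit called S1027 lower, with -0.51 ± 0.08 (edgeR adjusted p = 0.00357).

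With IPTG, edgeR called 33 features, 17 higher and 16 lower, with 424 at an unadjusted p under 0.05. In all, 13.4% of features had groups that did not overlap, where chance gives 10%. The authors' table lists 63, and 31 of the 33 are among them. The replicate letter as a block gave 32 in the fit of 12 libraries, 29 of them among the 33, while a fit of the 6 libraries compared gave 12 features without the block and 203 with it, 55 higher and 148 lower, among them all 33. Without library A, B or D with IPTG the count was 17, 18 and 19, and DESeq2 called 76. The call of S341 ended in 10 of 14 alternatives (highest adjusted p = 0.23). Those of hag, S1026, rpmGB, secE and spo0B without some single libraries (highest adjusted p = 0.179, 0.136, 0.136, 0.101 and 0.0993) ended too, and those of bglC and lytH in the fit of their 6 libraries alone (adjusted p = 0.12 and 0.073).

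**Figure D3:**
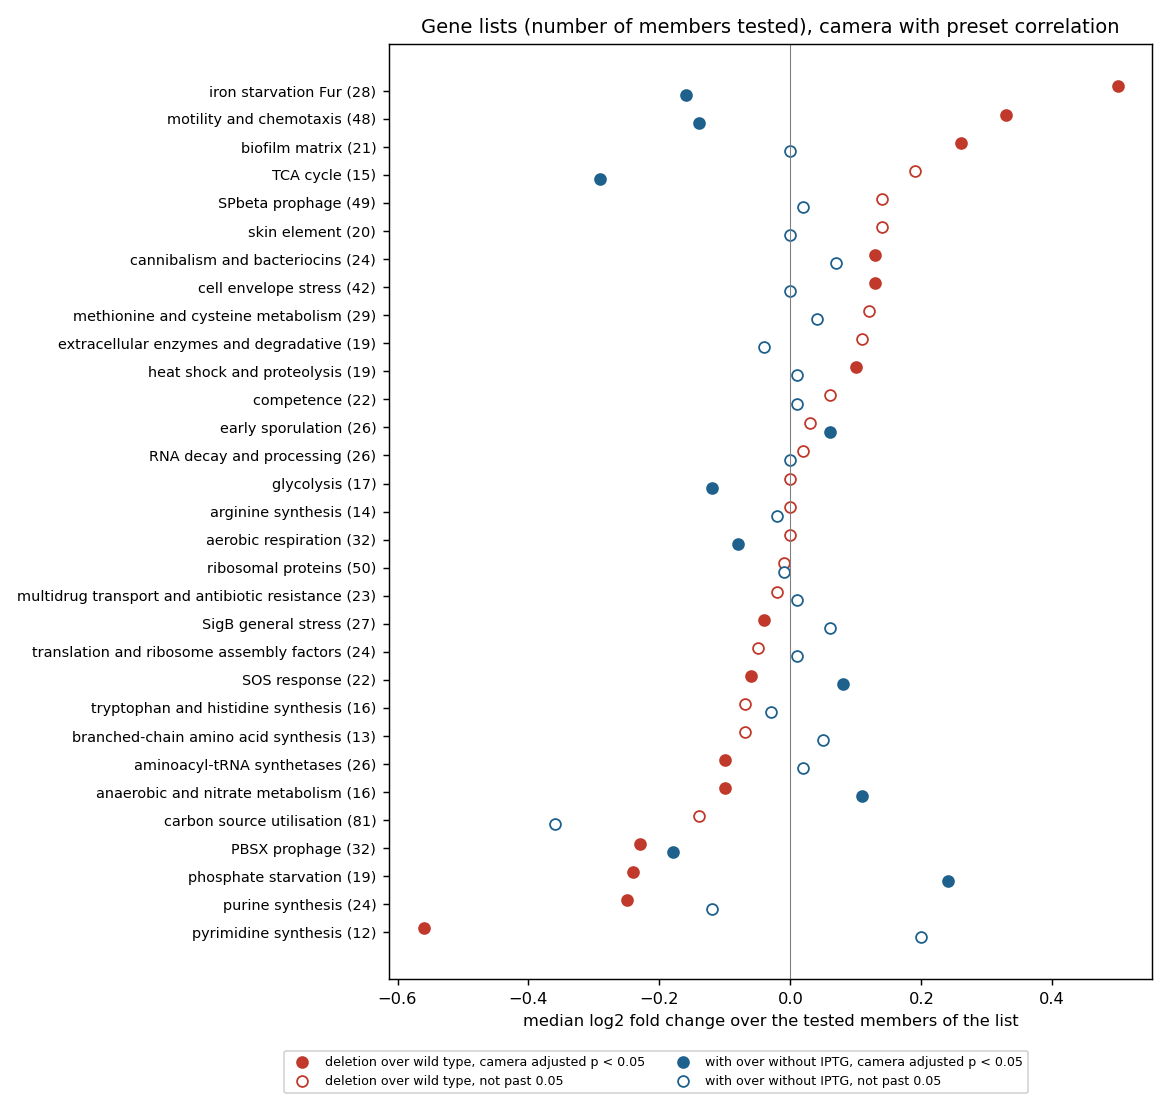
Median log2 fold change of each of the 31 tested gene lists in the deletion and IPTG comparisons (x axis; filled points, camera adjusted p under 0.05 with the preset correlation). Iron starvation genes lie at 0.50 in the deletion and -0.16 with IPTG, motility genes at 0.33 and -0.14.

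To find transcripts that respond both to the loss and to the supply of yacP, features called in both of these comparisons, which share no library, were counted. In total 12 features rose in the deletion and fell with IPTG, where independent lists would share 0.529 (one-sided Fisher's exact test across genes, p = 1.81e-15; genes are not independent replicates). They were the yrzI group of S1024, S1025, yrzI and S1026, the yheI group of S341, yheI and yheH, and bglC, hag, yhjG (0.44 and -0.59), ymcB (0.30 and -0.31) and ycnD (0.24 and -0.38). A further 3 features fell in the deletion and rose with IPTG, where 0.14 would be shared (one-sided Fisher's exact test, p = 0.000327): yacP, sigH (-0.43 and 1.34) and yqjD (-0.31 and 1.59). The class held yacP by construction, and sigH is its downstream neighbour, so this p-value is not evidence for transcripts elsewhere. Only yqjD lies away from that locus. Its level without IPTG was 84.6 to 94.8 CPM, against 252 to 259 CPM in the deletion and 267 to 285 CPM with IPTG. Without IPTG, hag lay at 17.9 to 20.6 CPM, under its 30.8 to 35.9 CPM in wild type. The 7 features of the yrzI and yheI groups lay at -0.47 to 0.57 (log2) of the deletion level without IPTG. Opposite calls thus do not mean like levels in the deletion and in the plasmid strain without IPTG. In edgeR, 0 features rose in both and 0 fell in both, while 13 and 17 did so at an unadjusted p under 0.05 in both, and 0 and 4 with DESeq2. S1024, S1025, yrzI, yheI and yheH kept both calls under every alternative run. The deletion calls of bglC and sigH ended without any 1 of the 6 libraries (highest adjusted p = 0.11 and 0.0822). The count of 12 was 7 without wild-type library B, 6 without library B or D with IPTG, 5 in fits of the 6 libraries alone, 30 in those fits with the letter as a block and 23 with DESeq2. The count of 3 was 1 without deletion library B, 7 with that block, 5 with DESeq2 and 10 without both plasmid-strain libraries D.

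**Figure D4:**
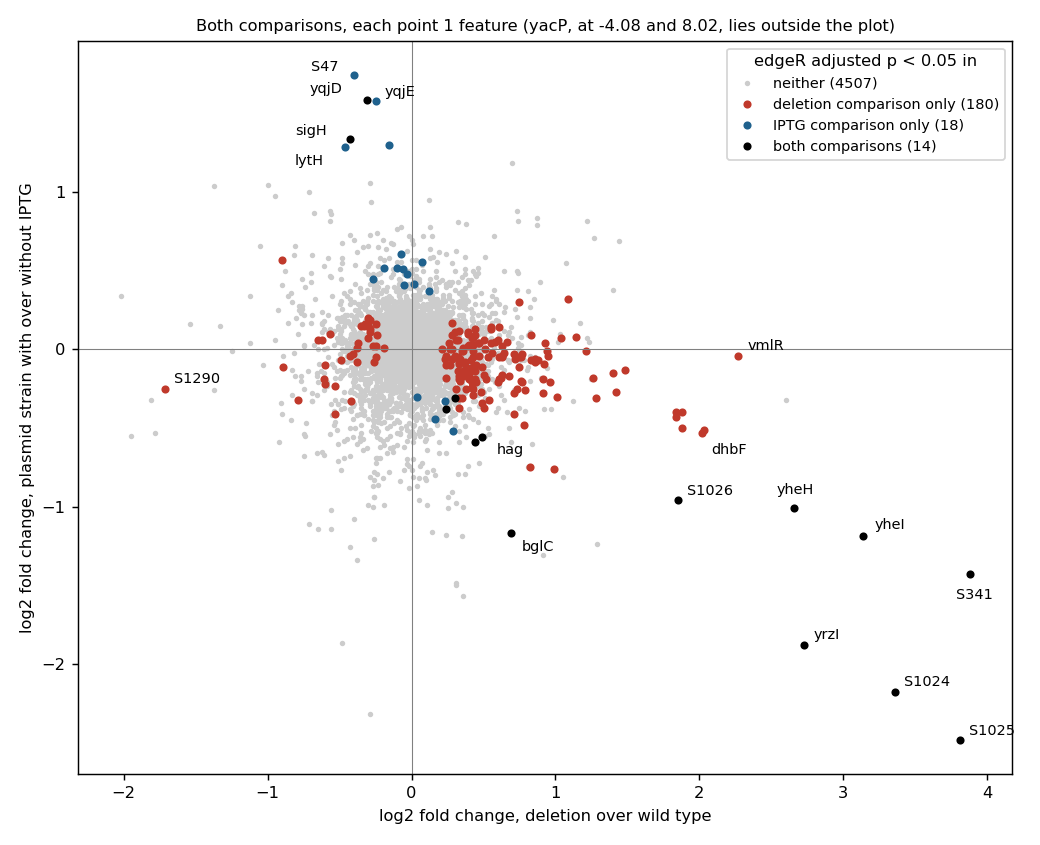
Log2 fold change in the deletion (x axis) against that with IPTG (y axis) for 4719 features, yacP left out. Points mark the 180 features called in the deletion alone, 18 with IPTG alone, 14 in both and 4507 in neither; S1025 lies farthest out at 3.81 and -2.49.

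The size of the deletion effect was also tested against that of lacking IPTG in the plasmid strain. It was larger in the deletion for vmlR, by 2.24 ± 0.13 (edgeR adjusted p = 1.2e-05), yheI, by 1.95 ± 0.14, yheH, by 1.65 ± 0.14, and the bacillibactin gene dhbF, by 1.49 ± 0.22. For S1025 and S1024 the difference was 1.32 ± 0.17 and 1.18 ± 0.16. In all, 37 features differed, 32 with a positive and 5 with a negative difference, and 555 had an unadjusted p under 0.05. A positive difference can also come from a larger change with IPTG. That was so for yacP, S47, yqjE, S906, yqjD (-0.31 in the deletion, 1.59 with IPTG) and sigH (-0.43 and 1.34). Without wild-type library D the count was 24, without deletion B or D 23, without both plasmid-strain libraries D 88, and DESeq2 gave 98.

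The plasmid strain without IPTG was compared with the deletion strain, which per the labels lacks the plasmid. The labels do not assign the antibiotics to strains. Strain, plasmid and antibiotic may therefore differ together, and their effects cannot be told apart. The Clp ATPase gene clpE rose by 4.68 ± 0.10 (log2 fold change ± SE, n = 3 per group; edgeR adjusted p = 6.98e-10), from 45.8 ± 1.96 to 1170 ± 150 CPM. S492 rose by 4.67 ± 0.28, yvdS, of the small multidrug resistance family, by 3.86 ± 0.13, and yacP by 5.39 ± 0.22. S491 had 2.45 CPM against 0.0554 CPM. The mannose genes manP and manA fell, with -5.31 ± 1.29 (adjusted p = 0.00687) and -5.44 ± 1.15 (adjusted p = 0.00321). In the plasmid strain, manP stood at 5.6, 3.34 and 103 CPM in libraries A, B and D, and its value ranged from -8.34 to -4.76 over the alternatives. The regulator gene manR fell with -3.36 ± 1.01 (adjusted p = 0.0196), a call that ended without library A lacking IPTG (adjusted p = 0.0659). S439 and S440 went from 14 and 7.58 CPM to 0.248 and 0.184 CPM. Of the yrzI features, S1025 lay at -0.07 (adjusted p = 0.614), S1024 at 0.04 (adjusted p = 0.797) and yrzI at 0.24 (adjusted p = 0.328), and S1026 was higher by 0.57 (adjusted p = 0.00917), while yheI was lower by a log2 fold change of -0.47 (adjusted p = 0.00252) and yheH by -0.40 (adjusted p = 0.00595).

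By list, the counts here are of called members, where 46.59% of all features were called; camera was not run, and brackets give the counts adjusted over the list alone. Biofilm genes had 19 of 21 higher and 1 lower (19 and 1), with epsN of exopolysaccharide synthesis at 1.87 ± 0.14, and all 32 PBSX genes were higher (32), with xkdX at 1.22 ± 0.11. Iron starvation genes had 24 of 28 lower (24), ykuP by -2.38 ± 0.13 and yfmC by -1.23 ± 0.07, and motility 32 of 48 lower and 1 higher (32 and 1), fliM by -0.97 ± 0.06. Purine synthesis had 18 of 24 higher and 3 lower (19 and 3), purQ by 1.13 ± 0.15 and guaB by -0.82 ± 0.09, pyrimidine synthesis 9 of 12 higher (9), and cell envelope stress 18 of 42 higher (18), sigW by 0.74 ± 0.07. In the TCA cycle 11 of 15 were lower (11), mdh by -1.16 ± 0.18. In carbon source utilisation 27 of 81 were lower and 3 higher (24 and 3). Library D of the plasmid strain lay apart in these TCA, carbon and purine genes and library A in the pyrimidine genes, as given above, and without both libraries D 13 TCA genes and 72 carbon genes were lower. Glycolysis had 12 of 17 lower (14), pgi by -0.89 ± 0.07. Aminoacyl-tRNA synthetases had 15 of 26 lower (15), metS by -0.66 ± 0.05, and methionine and cysteine metabolism 13 of 29 lower (12), mtnB by -1.53 ± 0.16. Respiration had 17 of 32 lower and 3 higher (18 and 3), cydC by 1.18 ± 0.13 and resA by -0.46 ± 0.07, and heat shock 11 of 19 higher and 5 lower (11 and 6), ctsR by 0.71 ± 0.06.

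The numbers of called members higher and lower, with brackets as before, were for the SOS response 10 and 1 (10 and 1), with uvrA at 0.37 ± 0.06, for multidrug transport 10 and 8 (12 and 8), with vmlR at -1.49 ± 0.09, and for competence 4 and 6 (5 and 6), with comEA at 3.21 ± 0.50. They were 8 and 4 (8 and 5) for early sporulation, with spoIID at 1.14 ± 0.16, 11 and 6 (9 and 6) for SPbeta, with nrdEB at 1.98 ± 0.18, and 6 and 1 (5 and 1) for the skin element. Ribosomal proteins had 12 and 7 (8 and 7), with rpmB at -0.47 ± 0.07, translation factors 6 and 6 (7 and 9), with ffh at 1.15 ± 0.12, and RNA decay 5 and 8 (6 and 10), with pnpA at 0.48 ± 0.09. SigB had 7 and 3 (7 and 3), arginine 5 and 0 (4 and 0), branched-chain amino acids 1 and 0 (1 and 0), and tryptophan and histidine 8 and 1 (8 and 2). Anaerobic metabolism had 6 and 2 (6 and 2), cannibalism 3 and 4 (1 and 2), extracellular enzymes 1 and 7 (1 and 7) and phosphate starvation 6 and 2 (6 and 2). At the rae1 locus 9 of 17 were higher and 1 lower (9 and 1), and of the reported targets, not independent evidence, 1 was higher and 2 lower (1 and 2). In all, edgeR called 2199 features, 1124 higher and 1075 lower. There were 2569 at an unadjusted p under 0.05 and 54.5% of features with groups that did not overlap, where chance gives 10%.

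The plasmid strain with IPTG was compared with wild type to see how far transcripts lay from wild type with yacP supplied. Strain, plasmid and IPTG differ together here, and the antibiotic may too, so differences cannot be credited to any of them alone. Supplied yacP stood 9.32 ± 0.26 above wild type (log2 fold change ± SE, n = 3 per group; edgeR adjusted p = 3.78e-09), while yheI and yheH remained higher by 1.48 ± 0.10 (adjusted p = 3.61e-06) and 1.25 ± 0.10, S1025 by 1.25, S1024 by 1.21, yrzI by 1.09 and S1026 by 1.46. S341 had 1.35 CPM against 0.202 CPM. As in the comparison above, clpE (4.86 ± 0.10, adjusted p = 5.17e-10) and S492 (4.39 ± 0.27) were higher, as was yonX (4.01 ± 0.33, adjusted p = 1.07e-05), and S491 had 1.93 CPM against 0 counts in all wild-type libraries. The mannose genes manP (-6.99 ± 1.40, adjusted p = 0.00241), manA (-7.13 ± 1.25) and manR (-4.38 ± 1.06, adjusted p = 0.00676) were lower, with manP at 5.45, 3.54 and 37.3 CPM in libraries A, B and D and a range of -8.82 to -6.52 over the alternatives. S439 and S440 had 17.2 and 10.7 CPM in wild type and 0.0312 CPM each with IPTG.

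With brackets for counts adjusted over the list alone, biofilm genes had 19 of 21 higher (19), epsN by 1.86 ± 0.14, PBSX 30 of 32 higher (31), and cell envelope stress 26 of 42 higher (26), yuaG by 1.92 ± 0.15. Iron starvation genes had 23 of 28 lower (23), efeU by -0.97 ± 0.06, and motility 32 of 48 lower and 2 higher (33 and 3), hag by -1.36 ± 0.08. In the TCA cycle 12 of 15 were lower (12), icd by -1.18 ± 0.19, and in carbon source utilisation 52 of 81 were lower and 3 higher (61 and 3), sacB by -1.41 ± 0.19. Without both plasmid-strain libraries D, which lay apart in the TCA and carbon genes, 14 and 70 were lower. Glycolysis had 16 of 17 lower (16), pgi by -0.96 ± 0.07, respiration 23 of 32 lower and 3 higher (24 and 3), qoxD by -0.48 ± 0.07, methionine and cysteine metabolism 16 of 29 lower (17), metN by -1.03 ± 0.12, and aminoacyl-tRNA synthetases 18 of 26 lower (18), metS by -0.67 ± 0.05. Multidrug transport had 12 higher and 5 lower of 23 (13 and 5). In the skin element list, the arsenic genes arsB and arsC lay at 1.88 ± 0.11 and 1.75 ± 0.09. Heat shock had 11 higher and 2 lower of 19 (11 and 2), ctsR by 1.12 ± 0.07, and early sporulation 11 and 3 of 26 (11 and 3), sigH by 1.29 ± 0.09 and spo0B by 0.98 ± 0.08.

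With the same brackets, called members higher and lower were 13 and 2 (14 and 2) for the SOS response, with lexA at 0.39 ± 0.06, 11 and 6 (12 and 6) for competence, with nin at -0.75 ± 0.09, 18 and 2 (16 and 2) for SPbeta, with yopA at 1.07 ± 0.08, and 9 and 1 (9 and 1) for the skin element. Purine synthesis had 9 and 3 (9 and 3), with guaB at -0.75 ± 0.09, and pyrimidine synthesis 7 and 1 (7 and 1). Ribosomal proteins had 7 and 6 (2 and 5), with rpmGB at 0.63 ± 0.08 and rpmB at -0.63 ± 0.07, translation factors 5 and 9 (5 and 9), with obg at 0.90 ± 0.07, and RNA decay 3 and 8 (2 and 7). SigB had 5 and 3 (5 and 3), arginine 4 and 0 (0 and 0), tryptophan and histidine 3 and 2 (3 and 2), and anaerobic metabolism 7 and 2 (7 and 2). Branched-chain amino acids had 0 and 0 of 13 in edgeR (0 and 0), with 0 at an unadjusted p under 0.05 and 0 in DESeq2. Cannibalism had 7 and 0 (6 and 0), extracellular enzymes 0 and 5 (0 and 3), and phosphate starvation 6 and 3 (6 and 3). At the rae1 locus 9 of 17 were higher and 1 lower (9 and 1), and of the reported targets, not independent evidence, 4 were higher (4). In all, edgeR called 2306 features, 1213 higher and 1093 lower. There were 2654 at an unadjusted p under 0.05 and 60.4% of features with groups that did not overlap, where chance gives 10%.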

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

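The tests of the difference between the effects were chosen in advance; in this part, the tests chosen only after the result was seen are the choice of how the splits are scored and those of the 3 patterns weighed below, except the test of the scaling. Each value here is the log2 fold change of the deletion over wild type minus that of the plasmid strain without over with IPTG, so it compares the deletion with the uninduced state of the plasmid strain, which still held yacP RNA (± SE, n = 3 libraries in each of 4 groups, edgeR). In all, 37 features differed. Of 100 combined splits of both sets of 6 libraries, 5 gave as many features or more, with 37 for the real split and 120 for the highest other, and all 5 kept the real deletion split. Scored by the larger of both orientations the real split gave 143 and the highest other 372, with 2 as large. The other splits that reached the real count each parted 1 letter pair of the plasmid strain. Within the real deletion split, the 3 other IPTG splits that part all 3 pairs gave 27, 5 and 26 as coded. By the larger orientation they gave 27, 30 and 26. Such splits are too few for a share under 0.05, and the share over all splits depends on the scoring, so chance is not excluded for this count as a whole.

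The difference was 3.94 ± 0.27 for yacP (adjusted p = 3.29e-05), which fell in the deletion and rose with IPTG by unequal amounts. It was 2.24 ± 0.13 for vmlR (adjusted p = 1.2e-05). For the transporter genes yheI and yheH it was 1.95 ± 0.14 and 1.65 ± 0.14 (adjusted p = 3.39e-05 and 0.00013). Bacillibactin genes differed by 1.52 ± 0.25 (ybdZ), 1.49 ± 0.22 (dhbF), 1.48 ± 0.22 (dhbB), 1.45 ± 0.23 (dhbA) and 1.37 ± 0.26 (dhbE), and besA, for a bacillibactin esterase, by 0.97 ± 0.16. The flavodoxin gene ykuP differed by 1.25 ± 0.17. Around yrzI the difference was 1.32 ± 0.17 for S1025 and 1.18 ± 0.16 for S1024. At the yacP locus it was 1.35 ± 0.18 for S47 and 0.90 ± 0.12 for sigH. The genes yqjE and yqjD differed by 1.32 ± 0.12 and 1.29 ± 0.07, S906 beside them by 1.14 ± 0.17, and yolJ of the SPbeta prophage by 1.06 ± 0.19. Negative differences were -1 ± 0.14 for yqjL and -0.81 ± 0.12 for S673. The adjusted p of the genes from ybdZ on ranged from 1.2e-05 (yqjD) to 0.038 (dhbE).

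Without IPTG, the plasmid strain held more yacP RNA than wild type, yet the 7 features of the yrzI and yheI groups lay at -0.47 to 0.57 of the deletion level (log2), with S1026 called higher and yheI and yheH called lower. Spill-over of reads between the pooled libraries is argued against as the source of that yacP RNA, since the highest share of yacP in a deletion library from the same pool was 0.000735% and the lowest without IPTG was 0.0228%. Nor do the values look like features that simply follow the amount of yacP RNA: their median over wild type was 2.97, with a lowest value of 2.26. For such features it would have to be at or below 0. These values restate the pattern itself, so they are not a separate test. What stays open is that yacP RNA without IPTG may not give active Rae1, for example if it is not translated, which counts of RNA cannot test. A difference between the strains other than yacP stays open as well.

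Iron starvation genes and vmlR rose in the deletion (17 list members and vmlR, 18 features, median 1.34), but 0 of the 18 were called lower with IPTG in edgeR (median -0.22; of the 28 list genes, 7 at an unadjusted p under 0.05 and 1 with DESeq2), while 6 of the 18 were in the paired fit of the 6 libraries. In the plasmid strain without IPTG the set lay at a median of -0.63 against wild type, with 19 of the 28 list genes called lower, and whether a lack of Rae1 acts alike on it in both backgrounds stays open, since the set, with a median difference of 1.06 and 10 called different, was picked for this contrast. The choice among the scalings run mattered little: the lowest median of the set under any of them was 1.32, where scaling as the whole cause would bring it near 0. These scalings lay close together, with medians of all features from -0.02 to 0.01. They could hardly bring the set near 0, so they do not test scaling as a cause. The condition written beforehand also asked that every call stay, and 17 of the 18 did. It was thus met by the median alone, a reading chosen after that outcome was seen. The antibiotic of the cultures, mls or kan, cannot be told apart from the strains for vmlR, whose value without IPTG over wild type was 0.78, because the labels do not say which culture received which, and a biological effect of the deletion strain alone stays open, untested.

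With IPTG, sigH, S47, rpmGB and secE downstream of yacP rose. More copies of the chromosomal region is argued against, as the highest of the 3 genes next upstream was 0.04. Transcription running on from an induced yacP copy at that place stays open: the Spearman rho of value and distance was -0.78 over the 10 features downstream, but the pattern is itself the rise of the nearest, so this does not test it. Where the yacP copy sits is not given in the sources used here, so the plasmid would have to carry or have joined this region, a point these counts do not settle.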

How the results depend on the processing

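The tests chosen only after seeing the data are the fits of the 6 libraries compared with the letter as a block and those without both plasmid-strain libraries D. DESeq2 called 329 features in the deletion and 76 with IPTG, 23 reciprocal features and 98 for the difference of the effects, where edgeR called 195, 33, 12 and 37. A fit of only the 6 libraries compared gave 417, 12 and 5 (deletion, IPTG, reciprocal), and with the block 340, 203 and 30, and it has no separate value for the difference. Without both plasmid-strain libraries D the counts were 514 and 36, with 9 reciprocal and 88 different. Leaving out each library gave 72 to 128 in the deletion, 17 to 35 with IPTG, 6 to 11 reciprocal and 23 to 50 different, with fewer libraries in each such fit, and the cause of the other shifts was not tested. On leaving out each library, the comparisons of the plasmid strain with the deletion and with wild type ranged from 1702 to 2615 and from 1736 to 2324. Without both libraries D they gave 2735 and 2631, and with the 10 CPM filter 1676 and 1831. With an estimated correlation 0 lists passed in the deletion and 0 with IPTG (7 and 4 at an unadjusted p under 0.05), with fry, which asks if a list's genes move on balance, 10 and 5 (edgeR and camera: 14 and 10), and without single libraries 11 to 16 and 8 to 11.

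The letter as a block of the 12-library fit gave 207, 32, 2333 and 2417 features, 9 reciprocal, 36 different, and the same 14 and 10 lists. Same-letter deviations correlated at 0.26, 0.08 and 0.16 (A, B, D) between deletion and wild type, 0.07, -0.17 and 0.09 between the plasmid strain without IPTG and the deletion, and -0.04, -0.02 and 0.09 between the strain with IPTG and wild type. In each of these comparisons a letter lay under 0.1, so these share only a letter, and not every library correlated best with its own.

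Of 48 named features called in the deletion, 23 kept the call in every alternative and 25 lost it in 1 or more (134 of 759 values); with IPTG 11 of 25 kept it and 14 lost it (68 of 397). In the other comparisons 52 of 53 and 53 of 53 kept it. No called value changed sign; some values near 0 that were not called did, such as nusG in the deletion, from -0.04 to 0.05. Of named features not called, 23 of 53 in the deletion and 26 of 52 with IPTG passed in an alternative. RLE scaling, both filters, the tRNA features and the top 10 features left out kept every total within 1.5 times and the median of all features within 0.05 of 0. By direction, the 10 CPM filter moved the lower calls from 39 to 62 in the deletion and from 16 to 25 with IPTG, and the negative differences from 5 to 13. Depth limits features such as S341, S439, S440 and S491, which lay near 3 counts in some group.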

Other observations

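The tests of this part chosen only after the result was seen are the fit of the plasmid strain's 6 libraries with the letter as a block, the deviations of library D and the choice of splits for the reciprocal features. With the letters as pairs, 203 features differed with IPTG, 55 higher and 148 lower. Of the genes for using other carbon sources, 21 of 74 measured fell, such as licB with -1.47, bglP with -0.83 ± 0.10 and bglH with -0.77 ± 0.10, all for uptake or breakdown of plant glucosides. TCA cycle genes had 8 of 15 lower, iron starvation genes 6 of 28 lower, dhbF with -0.53 ± 0.06 (edgeR adjusted p = 0.00025), PBSX 6 of 32 lower, glycolysis 4 lower and motility 3 lower. Phosphate starvation had 5 of 19 higher, anaerobic metabolism 4 of 16 and early sporulation 3.

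Among single genes that rose in that paired fit were amtB for ammonium uptake by 1.13 ± 0.13 (adjusted p = 0.000214), nasB for nitrate assimilation by 1.08 ± 0.13 and glnK for a PII regulator by 0.95 ± 0.14. In the deletion their values were -1.37, -1 and -0.57, not called. A pair of abundant small RNAs fell, scr of the signal recognition particle with -0.63 ± 0.05 (adjusted p = 1.59e-05) and 6S RNA, ssrSA, with -0.57 ± 0.07. The gene of the trans-translation protein smpB rose by 0.52 and the neighbouring genes obg and spo0B by 0.40 and 0.51. None of these genes was picked before its values were seen.

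Plasmid-strain library D differed from A and B in the same direction with and without IPTG for some lists. Carbon source genes in it lay 1.97 and 1.53 above the other 2 libraries of the group (median log2, without and with IPTG), TCA genes 0.86 and 0.64 above, and purine genes at -0.50 and -0.29. Pyrimidine genes lay at -0.41 without IPTG and at 0 with it, and at 0.67 and 0.35 in library A.

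With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split of the deletion and wild type gave 195 features and the highest other 0, and 1 of 10 reached the real count. For the plasmid strain without IPTG against the deletion the values were 2199 and 0, and with IPTG against wild type 2306 and 0, each reached by 1 split. Lists past camera's test numbered 14 in the real split of the deletion and 13 in the highest other, and 10 and 8 with IPTG, again 1 split each. With IPTG, 2 of the 10 splits reached 33 features: the real one and one with 259, which points to a structure of the samples by letter. That split parted 1 pair of letters, and the 3 other splits that part all 3 pairs, as the real one does, gave 0. For the 12 reciprocal features, only the IPTG splits within the real deletion split bear on the count, since the other deletion splits called 0. Of these 10, again too few for a share under 0.05, 1 gave as many, the real one, and the highest other gave 4.

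Since sigH rose with IPTG, a hypothesis was that genes under SigH control rise with it. The bound was written before the list's median was seen, although the values of 2 members, spoVG (0.34) and kinA (0.23), had been. Over 21 measured genes of a SigH list, sigH left out, the median was 0.07 (SD 0.20), with 15 above 0. In the paired fit 1 was called. The rotation test fry, of limma, gave an unadjusted p of 0.123, and 0.23 in the paired fit. The median argues against these genes rising along with sigH, which rose by 1.34.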
